A study of Caenorhabditis elegans with 12 samples.

How the data were processed

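Total RNA was taken with Trizol from age-synchronised wild-type (N2) Caenorhabditis elegans that had grown from the first larval stage to the fourth (L4) at 20 °C on nematode growth medium (NGM) seeded with Escherichia coli OP50. The medium held 1000 µM of linoleic acid (LNA), gamma-linolenic acid (GLA) or dihomo-gamma-linolenic acid (DGLA), or the ethanol vehicle alone (1% v/v, the control). Biotin-labelled cRNA was hybridised to a whole-transcript Affymetrix array for this species, with 3 biological replicates in each of the 4 groups and 1 array per replicate, 12 arrays in all. Replicate numbers are not described as pairing samples across groups, and no batch, date or plate is given in the sources used here.

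The deposited table gives, per the labels, values that the authors made with RMA (robust multi-array average, which corrects background, normalises between arrays and summarises probes), and names the Affymetrix Expression Console and the Transcriptome Analysis Console. Versions and options are not given in the sources used here. The deposited values were taken as log2 signal per probe set (transcript cluster), normalised between arrays by the authors. Their range, the absence of negative or missing values and the near-equal quartiles of the 12 arrays bore this out. No raw intensities were used here, so background correction and summarisation were not repeated.

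All 29317 probe sets entered the fit. Control probe sets of the array itself were to be left out, but the sources used here give no probe type by which to recognise them, so the 3125 probe sets with no gene symbol stayed in. Of the others, 25546 carried exactly 1 gene symbol and 646 carried several. Of the first kind, 25495 matched the reference gene table (assembly WBcel235) by gene identifier, and 0 symbols changed by the match. That table served only for names, gene lengths (genomic span) and the neighbours of genes. The files name no genome build, so no coordinates are given. The values of 539 probe sets repeated those of another probe set on all 12 arrays. A gene was represented by its 1-symbol probe set with the highest mean over the 12 arrays, which gave 25478 genes.

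Group means were fitted to the log2 values of all 12 arrays with limma 3.58.1 (lmFit and eBayes, default settings) in R 4.3.3, with no block for replicate number. All 6 comparisons between the 4 groups were taken from that fit as two-sided moderated tests. The prior gave 3.60 degrees of freedom and the total was 11.6. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 over all probe sets of a comparison, with no limit on fold change and no filter on dim probe sets. Fold changes carry the standard error (SE) or the 95% interval of the fit. With 3 arrays per group the number of arrays limits the precision, and the median SE of a log2 fold change was 0.136.

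Gene lists and cell type markers, 45 in all, were written before the data were examined. Each was tested as a set with camera at a preset inter-gene correlation of 0.01, with adjustment over the 45 lists in a comparison. Camera was run again with the correlation estimated from the residuals of each list, and fry was run as a second set test. Members past the threshold were counted over all probe sets and again adjusted over the list alone. The list named peroxisome biogenesis holds not only peroxins (prx) but also peroxisomal transporters (pmp) and the peroxisomal catalase ctl-2.

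Genes to be named were also chosen by a rule fixed before the data were examined. For each acid against control these were the 8 genes with the highest and the 8 with the lowest fold change among called genes whose 3 treated values all lay on the same side of the 3 control values. For comparisons between acids the rule took 5 and 5. From a list, at most 4 called members with the smallest adjusted p were named, and 9 desaturases and elongases were always given. Genes outside the rule are marked as chosen after their values were seen.

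The 3 comparisons against control share the same 3 control arrays, so overlaps were set beside 100 simulated experiments in which unchanged groups shared 1 control group. The fit was tested on simulated data of the same size with 50 changed probe sets of each size in each comparison. In the simulated counterpart of LNA against control it recovered 26% of 50 changes of 0.5 on the log2 scale, 82% of 50 changes of 1 and 98% of 50 changes of 2, with 9 false calls among 160. For GLA against control the shares were 36%, 76% and 96%, with 7 false calls among 159, and for DGLA against control 24%, 88% and 98%, with 5 among 158. All simulated arrays of a probe set had the same spread and were drawn independently, with no arrays apart such as LNA 2 and LNA 3. These simulations differed only in the random draw and the group changed. They do not give the share recovered or the false calls of the real comparisons. In a simulated set of 45 lists with 1 shifted list, that list was the only 1 called. Genes were drawn independently of each other in that simulation, so it does not show how the list test behaves where genes are correlated.

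Alternatives fixed before the data were examined were a block for replicate number, a fit on only the 6 arrays compared, the trend and robust options of eBayes, array weights, removal of the dimmest 40% of probe sets, cyclic loess, centring of each array on its median, 1 probe set per gene, a fold limit of 2, an ordinary linear model with unadjusted p and a fold of 2, an unadjusted p in the second comparison of each overlap, and leaving out each array in turn. Added after the data were seen were fits without arrays LNA 2 and LNA 3 (which leave LNA with 1 array, assumed to vary like those of the other groups), removal of the trend of each array with gene length, counting repeated probe sets once, and the fit on 6 arrays for single genes. The length trend was a lowess curve of each array's deviation on log10 gene length within each of 4 equal bins of probe sets by mean signal. A curve over all probe sets together was tried first, and was replaced when it was seen to move few values. As a further test of gene length, each member of a list was set beside the 50 genes outside the list nearest to it in length within its bin of signal. For stage, the vitellogenin means of LNA 2 and LNA 3 were set against the SD of the other 10 arrays, which replaced a count of the arrays that lay between the pair, since that count left out the spread between arrays. Every split of the 6 arrays of a comparison into 3 and 3 was also fitted, with the other 6 arrays kept in their groups. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.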

Results

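RNA from wild-type Caenorhabditis elegans larvae raised to the L4 stage on 1 of 3 polyunsaturated fatty acids was measured on 12 whole-transcript arrays. The groups were vehicle control, linoleic acid (LNA), gamma-linolenic acid (GLA) and dihomo-gamma-linolenic acid (DGLA), with n = 3 arrays each and every acid at 1000 µM. GLA carries an added double bond relative to LNA, and DGLA is GLA lengthened by a carbon pair. Worms make these acids in that order, with the desaturase fat-3 turning LNA into GLA, the elongase elo-1 lengthening GLA, and the desaturase fat-4 using DGLA. Values are RMA log2 signals for 29317 probe sets, of which the 25546 with exactly 1 gene symbol stand for 25478 genes. Among those 25546, 18847 were of protein-coding genes, 5982 of non-coding RNA genes and 612 of pseudogenes. Array medians lay between 4.47 and 4.56, and correlations between arrays, taken across probe sets, lay between 0.9865 and 0.9944. The number of arrays limits the precision of every value given here.

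The first principal component held 23.1% of the variance and set arrays LNA 2 (41.95) and LNA 3 (35.68) apart from the other 10 arrays (-18.02 to 3.64), while array LNA 1 lay among them. The second component held 11.4%. LNA 2 and LNA 3 correlated with each other at 0.9924 and with the other 10 arrays at 0.9912 at most, and the lowest correlation among those 10 was 0.9908. Several gene lists that move with these arrays are given per array, and counts are given again without them, an alternative chosen after the data were seen. It leaves LNA with 1 array, which is assumed to vary like the arrays of the other groups, so a call that stays or ends there rests on that array alone.

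**Figure D1:**
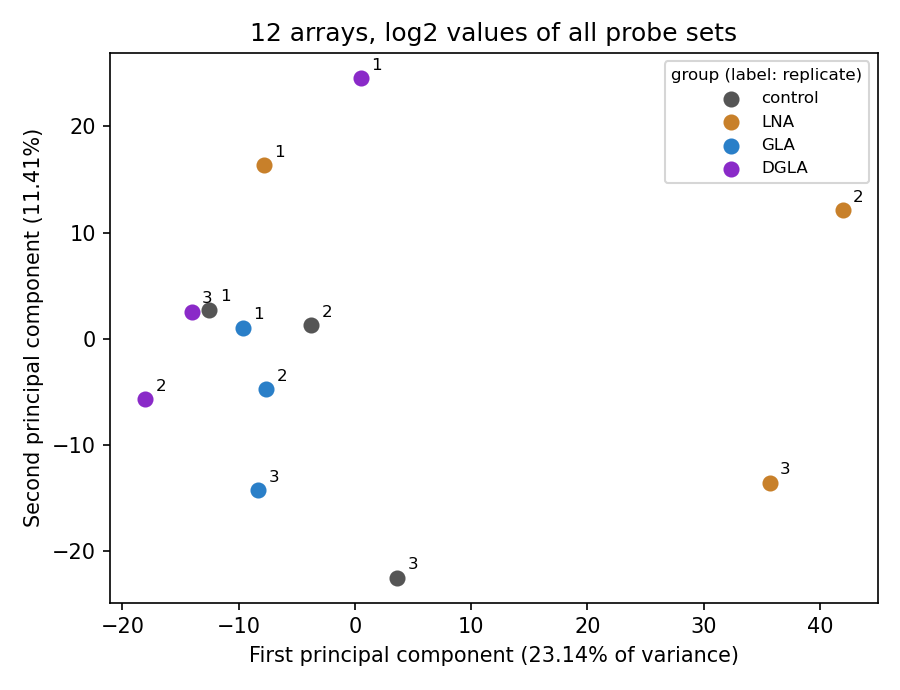
First (23.1% of the variance) against second (11.4%) principal component of the log2 RMA signal, with 1 point per array coloured by group. LNA 2 and LNA 3 lie at 41.95 and 35.68 on the first component, and the other 10 arrays lie between -18.02 and 3.64.

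The comparison of LNA with control asked which genes respond to the first of these acids in the pathway. The fatty acid and retinol binding family gene far-3 (F15B9.1) rose 8.47-fold, from 4.20 ± 0.153 to 7.28 ± 0.624 (log2 signal, mean ± SD, n = 3). The infection response gene irg-3 (F53E10.4) rose 4.22-fold, from 6.75 ± 0.182 to 8.83 ± 0.349, and fat-5 (W06D12.3), a palmitoyl-CoA desaturase, rose 3.93-fold, from 4.34 ± 0.271 to 6.31 ± 0.166. Genes of fatty acid breakdown went both ways. The acyl-CoA dehydrogenase acds-10 rose 2.06-fold and the carnitine palmitoyltransferase family gene cpt-3 rose 2.80-fold, whereas its relative cpt-4 fell by 1.05 on the log2 scale, from 7.69 ± 0.00566 to 6.65 ± 0.0704.

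In limma's moderated test 17 genes passed, 14 higher and 3 lower with LNA, and 7 and 3 of them changed at least 2-fold. Adjusted p was 0.000255 for fat-5, 0.000324 for far-3, 0.000324 for irg-3, 0.000473 for cpt-4 and 0.00354 for acds-10. In each of the 17 genes the 3 LNA arrays did not overlap the 3 control arrays, as was so for 3104 of all 25478 genes, where chance gives 10%. T25G12.13 rose 2.14-fold (adjusted p = 0.0206), and the dehydrogenase/reductase dhrs-4 (1.09 on the log2 scale, adjusted p = 0.0375) and the dienoyl-CoA reductase decr-1.1 (0.88, adjusted p = 0.017) also rose. The hydroxyacyl-CoA dehydrogenase hacd-1 (-1.29, adjusted p = 0.017) and the C-type lectin domain gene clec-174 (-1.23, adjusted p = 0.0226) were lower. Of the desaturases and elongases fixed for report, fat-5 alone passed, and elo-1 (0.38, adjusted p = 0.261), elo-2 (-0.33, adjusted p = 0.399), fat-7 (-0.18, adjusted p = 0.731), fat-1 (0.18, adjusted p = 0.561), fat-2 (-0.03), fat-3 (-0.05), fat-4 (0.16) and fat-6 (-0.03) did not.

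Fitted on the 6 LNA and control arrays alone, which leaves fewer samples for the spread, 0 probe sets passed, so every call here drew on the spread of the GLA and DGLA arrays as well. In the fit with those groups the calls of far-3, irg-3, fat-5, acds-10 and cpt-4 held whichever array of the comparison was left out. The calls of cpt-3 (adjusted p 0.0681 to 0.0922), T25G12.13 (0.0681 to 0.102) and decr-1.1 (0.0634 to 0.0922) ended without control 1, control 2, control 3 or LNA 2, and that of hacd-1 (0.0681 to 0.0922) without control 2, control 3 or LNA 2. Those of clec-174 (0.0681 to 0.153) and dhrs-4 (0.0569 to 0.195) ended without any 1 control array, LNA 2 or LNA 3. The count of 17 probe sets fell to 8 without control 1, 5 without control 2, 5 without control 3 and 6 without LNA 2. It was 895, with 191 higher and 704 lower, without LNA 1, which left the 2 arrays that lie apart. Without LNA 2 and LNA 3 it was 12, and 4 of these were among the 17, namely far-3, irg-3, fat-5 and cpt-4.

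As sets, 6 of the 45 gene lists shifted upward with LNA, and all 6 were lost when the correlation between genes was estimated (adjusted p = 0.84 with an estimated correlation for each). Of 43 beta-oxidation genes 2 rose and 2 fell, and 17 rose and 2 fell adjusted over the list alone (median 0.23, adjusted p = 9.73e-09). Of 17 fatty acid binding genes 1 rose, or 4 adjusted over the list alone (median 0.16, adjusted p = 8.32e-07), and of 16 peroxisome biogenesis genes none passed but 4 rose adjusted over the list alone (median 0.19, adjusted p = 0.000706). No single gene passed, on either adjustment, among 75 ribosomal proteins (median 0.11, adjusted p = 3.74e-07), 48 respiratory chain genes (median 0.10, adjusted p = 0.00201) and 60 neuropeptide genes (median 0.09, adjusted p = 0.00543). These 3 last lists moved with the arrays that lie apart, and their calls ended once the trend with gene length was removed. The ribosomal and neuropeptide tests turned direction without LNA 2 and LNA 3, and the respiratory and neuropeptide calls ended after cyclic loess. The ribosomal list deviated from its 12-array mean by -0.043, 0.15 and 0.1 in LNA 1, LNA 2 and LNA 3, the respiratory list by -0.009, 0.101 and 0.084, and the neuropeptide list by -0.065, 0.166 and 0.104. The beta-oxidation list (-0.053, 0.137 and 0.007) was also higher in LNA 2 and LNA 3 than in LNA 1. So were the peroxisome biogenesis list (-0.054, 0.074 and 0.01) and the fatty acid binding list (0.005, 0.232 and 0.119). In these 3 lists every LNA array lay above every control array. The neuropeptide call ended without control 3 (adjusted p = 0.0824), LNA 2 (0.36) or LNA 3 (0.056), and the count of 6 lists was 12 without LNA 1 and 2 without LNA 2 and LNA 3. The 2 that then stayed were beta-oxidation and fatty acid binding.

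The comparison of GLA with control asked the same of the acid with the added double bond. The largest rise was again in far-3, 32.5-fold to 9.22 ± 0.155. The cytochrome P450 gene cyp-13A12 (F14F7.3) rose 13.7-fold, from 4.08 ± 0.17 to 7.86 ± 0.0826, the UDP-glucuronosyltransferase gene ugt-37 (F10D2.6) rose 7.07-fold, from 5.40 ± 0.233 to 8.22 ± 0.0256, and irg-3 rose 6.70-fold. Lower with GLA were mbug-1 (F55G11.4), from 6.12 ± 0.276 to 4.08 ± 0.0498, and the C-type lectin domain gene clec-247 (Y51A2A.1), which fell by 1.64 on the log2 scale. The infection response gene irg-5 (F35E12.5) fell by 1.56.

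In limma's test 67 probe sets passed, 43 higher and 24 lower, for 42 and 21 genes, and 20 and 10 genes changed at least 2-fold. None of the called genes had overlapping arrays between the groups, as was so for 12% of all genes, where chance gives 10%. Adjusted p was 3.15e-07 for cyp-13A12, 2.11e-06 for far-3, 7.33e-06 for ugt-37, 8.76e-06 for irg-3, 2.95e-05 for clec-247, 8.32e-05 for mbug-1 and 0.0136 for irg-5. Next among the rises came the beta-carotene oxygenase bcmo-1 (1.80, adjusted p = 0.0124), T25G12.13 (1.62, adjusted p = 0.000466), Y87G2A.2 (1.41, adjusted p = 0.00123) and cyp-13B1 (1.34, adjusted p = 0.00307). Among the falls came the claudin-like clc-19 (-1.49, adjusted p = 0.0191), cyp-35A3 (-1.43, adjusted p = 0.0215), hacd-1 (-1.19, adjusted p = 0.00986), clec-174 (-1.12, adjusted p = 0.019) and F22H10.2 (-1.08, adjusted p = 0.0191). The desaturase fat-5 rose 2.24-fold (adjusted p = 0.00401). The other fixed enzymes did not pass, with fat-7 (0.56, adjusted p = 0.536), elo-2 (-0.23), elo-1 (0.19), fat-3 (0.19), fat-1 (0.14), fat-4 (0.05), fat-2 (0.00013) and fat-6 (-0.0069).

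The calls of far-3, cyp-13A12, ugt-37, irg-3, T25G12.13, Y87G2A.2, cyp-13B1, mbug-1, clec-247 and fat-5 held whichever array was left out. The calls of bcmo-1 (0.0516 to 0.0739) ended without control 1, GLA 2 or GLA 3, of clc-19 (0.0555 to 0.114) without control 1, control 2 or any 1 GLA array, and of cyp-35A3 (0.0502 to 0.116) without any 1 of the 6 arrays. The calls of clec-174 (0.0623 to 0.0998) ended without control 1, control 2, GLA 1 or GLA 2, of F22H10.2 (0.0917 to 0.0982) without control 1, control 2, GLA 1 or GLA 3, of irg-5 (0.0577 to 0.0808) without control 2 or any 1 GLA array, and of hacd-1 (0.0556 to 0.0611) without control 2, GLA 1 or GLA 3. The count of 67 probe sets was 33 without control 1, 35 without control 2, 30 without GLA 1, 24 without GLA 2 and 32 without GLA 3, and 56, of which 51 were among the 67, without LNA 2 and LNA 3. The call of cyp-35A3 ended there too. On the 6 arrays alone the count was 27, of which 26 were among the 67, and the calls of bcmo-1, cyp-13B1, clc-19, hacd-1, clec-174, F22H10.2 and fat-5 ended.

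With GLA 9 lists shifted. Of the 43 beta-oxidation genes 7 rose and 2 fell, or 11 and 2 adjusted over the list alone (median 0.10, adjusted p = 1.03e-08, adjusted p = 0.601 with an estimated correlation). The acyl-CoA oxidases acox-1.1 (1.02, adjusted p = 0.00094) and acox-3 (0.85, adjusted p = 0.00831) and the thiolase daf-22 (0.94, adjusted p = 0.00692) rose, and cpt-4 fell (-0.70, adjusted p = 0.0065). Of 46 innate immune effectors 1 rose and 4 fell, or 1 and 13 adjusted over the list alone (median -0.12, adjusted p = 1.03e-08, adjusted p = 0.287 with an estimated correlation). Besides irg-3 and irg-5, sysm-1 fell (-0.97, adjusted p = 0.0065) and irg-4 fell (-0.99, adjusted p = 0.00831). Calls of daf-22, cpt-4, sysm-1 and irg-4 ended on the 6 arrays alone. The call of daf-22 ended without GLA 2 (0.0542), that of irg-4 without GLA 2 (0.0556), and that of acox-3 (0.0518 to 0.0562) without control 1, GLA 1 or GLA 2.

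Further lists shifted with GLA, but none of these held with an estimated correlation. That gave adjusted p = 0.601 for peroxisome biogenesis, molting and sperm genes, 0.663 for glutathione S-transferases, 0.77 for SKN-1 and oxidative stress, and 0.845 for ribosomal proteins and oocyte genes. Peroxisome biogenesis genes rose as a set (median 0.19, adjusted p = 3.59e-05), with none passing singly and 5 adjusted over the list alone. The ribosomal proteins (median 0.05, adjusted p = 0.00039) and the 71 molting genes (median 0.09, adjusted p = 0.00124) also rose as sets with no member passing. Of 43 genes of SKN-1 and oxidative stress none passed, and 2 rose and 1 fell adjusted over the list alone (median 0.09, adjusted p = 0.000765). Of 48 glutathione S-transferases gst-44 rose (0.80, adjusted p = 0.00855), or 3 members adjusted over the list alone (median 0.09, adjusted p = 0.00167). The 63 sperm genes (median -0.09, adjusted p = 0.00959) and the 30 oocyte and eggshell genes (median -0.08, adjusted p = 0.0319) were lower as sets with no member passing. Without control 3 the calls of sperm (0.21), molting (0.21), oocyte (0.948) and ribosomal genes (0.0619) ended, and without GLA 1 those of sperm (0.0675) and oocyte genes (0.624). The oocyte test turned direction without control 3, and its call ended after cyclic loess, without dim probe sets and with the length trend removed. The call of gst-44 (0.0505 to 0.0666) ended without control 1, control 2, GLA 2 or GLA 3, and on the 6 arrays alone. All 9 lists called with GLA stayed called without LNA 2 and LNA 3.

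The comparison of DGLA with control asked the same of the elongated acid, and it held the most calls of the 3. With DGLA, far-3 rose 29.5-fold, to 9.09 ± 0.153, irg-3 rose 6.93-fold, cyp-13A12 rose 5.44-fold and nta-1 (F12E12.11) rose 5.32-fold, from 5.22 ± 0.126 to 7.63 ± 0.314. The glutathione S-transferase gst-33 rose 4.02-fold and the cadmium responsive gene cdr-4 rose 3.69-fold. The steepest fall was in irg-5, from 9.94 ± 0.24 to 6.88 ± 0.243, which was 8.33-fold lower, and clec-174 was 4.62-fold lower. Genes of successive steps of peroxisomal beta-oxidation rose, namely acox-1.1 (2.23-fold), the hydratase maoc-1 (2.43-fold), the hydroxyacyl-CoA dehydrogenase dhs-28 (1.77-fold) and daf-22 (2.23-fold).

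In limma's test 146 probe sets passed, 88 higher and 58 lower, for 84 and 54 genes, and 37 and 21 genes changed at least 2-fold. None of the called genes had overlapping arrays between the groups, as was so for 10.8% of all genes, where chance gives 10%. Adjusted p was 2.82e-06 for cdr-4, 2.89e-06 for far-3, 8.72e-06 for irg-3, cyp-13A12 and nta-1 alike, 4.09e-05 for irg-5, 5.07e-05 for clec-174 and 0.000421 for gst-33. Also higher were T16G1.7 (1.97, adjusted p = 0.00374) and F25D1.5 (adjusted p = 1.5e-05), whose control mean of 2.35 lay below the lower quartile of every array, so that no fold is given for it. Also lower were F09C8.1 (-1.80, adjusted p = 0.000133), mbug-1 (-1.65, adjusted p = 0.000216), clec-71 (-1.58, adjusted p = 0.000575), F55G11.8 (-1.53, adjusted p = 0.000186), F55G11.2 (-1.50, adjusted p = 0.00184) and clec-247 (-1.41, adjusted p = 5.47e-05). The desaturase fat-5 rose 2.57-fold (adjusted p = 0.000544). The other fixed enzymes did not pass, with fat-7 nearest (0.81, SE 0.161, adjusted p = 0.0614), then fat-1 (0.32, adjusted p = 0.414), fat-3 (0.39, adjusted p = 0.417), elo-1 (0.27), fat-6 (0.22), fat-2 (0.14), fat-4 (0.06) and elo-2 (0.0062). Each named gene called in this paragraph stayed called whichever array was left out. The count of 146 probe sets was 89 without control 1, 94 without control 2, 90 without DGLA 2 and 91 without DGLA 3, and 127, of which 116 were among the 146, without LNA 2 and LNA 3. Fitted alone, the 6 arrays compared gave 66, of which 65 were among the 146.

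**Figure D2:**
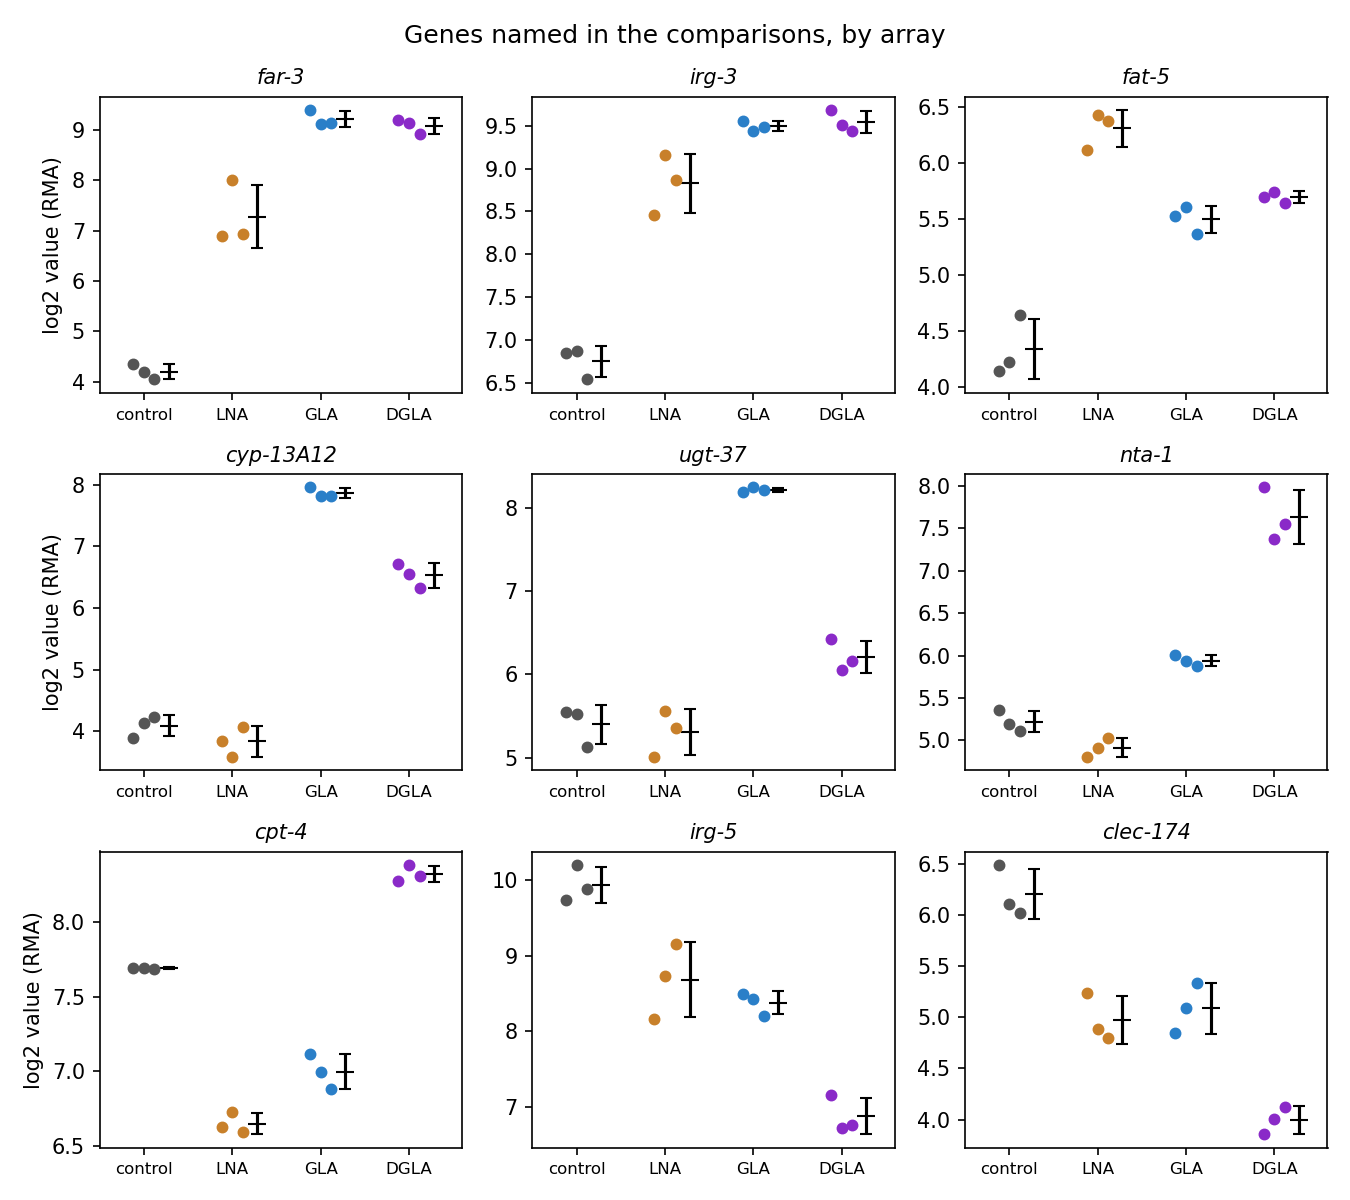
Log2 RMA signal of 9 genes in the 4 groups, with 1 point per array and bars giving the mean ± SD of 3 arrays. The gene far-3 goes from 4.20 in control to 7.28 with LNA, 9.22 with GLA and 9.09 with DGLA, and irg-5 from 9.94 in control to 6.88 with DGLA.

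Innate immune effectors had the smallest adjusted p of the lists with DGLA, though not the largest median. Of 46 genes 1 rose and 12 fell, or 2 and 16 adjusted over the list alone (median -0.15, adjusted p = 3.19e-17), and this was the only list call of any comparison that held with an estimated correlation (adjusted p = 0.0363). Besides irg-3 and irg-5, F55G11.8 and C17H12.8 (-0.84, adjusted p = 0.00117) passed with the smallest adjusted p. Of the 43 beta-oxidation genes 10 rose and none fell, or 21 and 3 adjusted over the list alone (median 0.28, adjusted p = 9.67e-16, adjusted p = 0.263 with an estimated correlation), with acox-1.1 (adjusted p = 0.000161), maoc-1 (0.000603), daf-22 (0.000658) and dhs-28 (0.00127) foremost. Of the 16 peroxisome biogenesis genes 3 rose, or 10 and 1 fell adjusted over the list alone (median 0.43, adjusted p = 1.58e-11, adjusted p = 0.123 with an estimated correlation). These were the peroxisomal catalase ctl-2 (0.66, adjusted p = 0.0221), the peroxin prx-2 (0.68, adjusted p = 0.0268) and the peroxisomal transporter pmp-2 (0.68, adjusted p = 0.0378). Their calls ended without single arrays, ctl-2 (0.0754 to 0.104) without control 1, control 3 or any 1 DGLA array, prx-2 (0.0548 to 0.131) without control 2, control 3 or any 1 DGLA array, and pmp-2 (0.0673 to 0.172) without any 1 of the 6 arrays. These 3 gene calls ended on the 6 arrays alone as well. The call of each of these 3 lists held whichever array was left out.

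A further 12 lists shifted with DGLA. Of 19 desaturases and elongases fat-5 rose, or 5 genes adjusted over the list alone (median 0.11, adjusted p = 0.000289, adjusted p = 0.351 with an estimated correlation). Of 31 acyl-CoA synthetase and binding genes 2 rose, or 5 adjusted over the list alone (median 0.03, adjusted p = 0.0086), of 43 SKN-1 and oxidative stress genes 4 rose, or 8 and 1 fell adjusted over the list alone (median 0.04, adjusted p = 0.00354), and of 48 glutathione S-transferases 3 rose, or 4 and 1 fell adjusted over the list alone (median 0.06, adjusted p = 0.0476). With an estimated correlation these had adjusted p = 0.263, 0.619 and 0.62. The transferases gst-33 and gst-5 (1.13, adjusted p = 0.00127) were called. Of 48 lipase and lipid droplet genes none passed and 3 rose adjusted over the list alone (median 0.09, adjusted p = 0.00338, adjusted p = 0.291 with an estimated correlation), of 71 molting genes 1 rose, or 2 adjusted over the list alone (median 0.07, adjusted p = 0.00461, adjusted p = 0.351 with an estimated correlation), and of 17 fatty acid binding genes far-3 alone rose on either adjustment (median 0.085, adjusted p = 0.0151, adjusted p = 0.508 with an estimated correlation). No member passed among 17 phosphatidylcholine and SAM synthesis genes (median 0.09, adjusted p = 0.00232, adjusted p = 0.263 with an estimated correlation), 22 lipid regulators (median 0.12, adjusted p = 0.0107, adjusted p = 0.327 with an estimated correlation) and 14 pharynx markers (median 0.11, adjusted p = 0.0421, adjusted p = 0.263 with an estimated correlation). Of 16 iron and ferroptosis genes 2 rose adjusted over the list alone (median 0.07, adjusted p = 0.038, adjusted p = 0.515 with an estimated correlation), and the sperm genes were lower as a set (median -0.05, adjusted p = 0.037, adjusted p = 0.444 with an estimated correlation).

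Of these 12 lists only desaturases and elongases stayed called whichever array was left out. The calls of the other 11 ended without DGLA 1 for SKN-1 and oxidative stress (0.143), phosphatidylcholine and SAM synthesis (0.0548) and without either control 1 or DGLA 1 for lipid regulators (0.0551 and 0.143) and glutathione S-transferases (0.217 and 0.306). They ended without control 3 for acyl-CoA synthetases (0.0521) and molting (0.54), and without control 1 for lipases (0.06). They ended without control 1, control 3 or DGLA 1 for fatty acid binding (0.0537 to 0.125) and iron and ferroptosis genes (0.104 to 0.394), without control 1, control 3, DGLA 1 or DGLA 3 for pharynx markers (0.0864 to 0.151), and without control 2, control 3, DGLA 2 or DGLA 3 for sperm genes (0.0537 to 0.334). The count of 15 lists was 8 without DGLA 1. With LNA 2 and LNA 3 left out it was 14, all among the 15, and the call of glutathione S-transferases ended, as it did after cyclic loess and after median centring. That of pharynx markers ended after median centring and without dim probe sets, and that of iron and ferroptosis genes without dim probe sets.

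**Figure D3:**
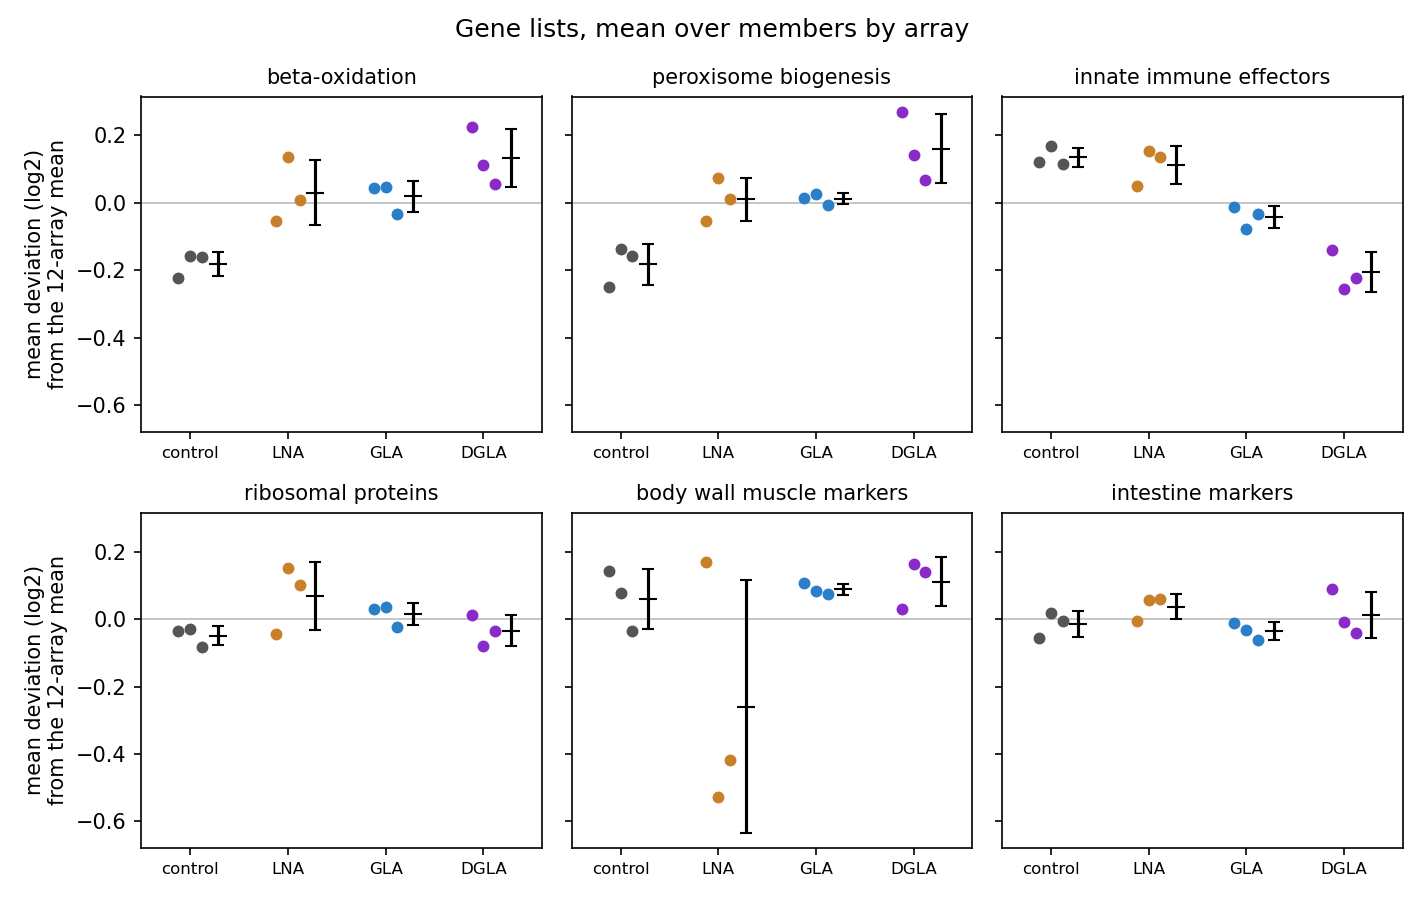
Mean deviation of 6 gene lists from their 12-array mean (log2), with 1 point per array and bars giving the mean ± SD of 3 arrays. The control arrays lie at -0.224, -0.159 and -0.161 for beta-oxidation, and the muscle markers lie at 0.168, -0.527 and -0.419 in LNA 1, LNA 2 and LNA 3.

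The other 26 lists passed with none of the acids against control, and the lowest of each list's 3 adjusted p values follows. It was 0.0547 for 17 body wall muscle markers, 0.0581 for 23 neuron markers, 0.0686 for 31 autophagy genes, 0.0793 for 53 germline genes, 0.095 for 34 proteasome genes and 0.0961 for 247 C-type lectins. It was 0.125 for 36 DAF-2/DAF-16 genes, 0.131 for 47 genes of glycolysis, glyoxylate and gluconeogenesis, 0.17 for 28 apoptosis, 10 fatty acid synthesis and 9 histone genes, and 0.182 for 5 coelomocyte markers. It was 0.227 for 18 heat shock genes, 67 UDP-glycosyltransferases and 5 vitellogenins, 0.311 for 172 cuticle collagens, 0.448 for 19 intestine markers, 0.449 for 54 epidermal antimicrobial peptides and 0.481 for 12 hypodermis markers. It was 0.521 for 11 vulva and uterus markers, 0.596 for 27 genes of the ER unfolded protein response, 0.617 for 40 insulin-like peptides, 0.669 for 8 excretory and seam markers, 0.727 for 9 spermatheca and sheath markers, 0.775 for 15 mitochondrial stress genes and 0.776 for 74 cytochrome P450 genes. Single members of the families passed both ways. With DGLA 4 cytochrome P450 genes rose and 2 fell, 2 UDP-glycosyltransferases rose and 3 fell, and 2 C-type lectins rose and 5 fell. The median, the mean and the test of a list differed in sign for 10, 6 and 3 lists with LNA, GLA and DGLA, and for 15, 7 and 12 in the comparisons between acids, and none of these lists was called.

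Calls were counted that the acids had in common. Of 158 genes called with any acid, 12 were called with all 3. Of these 10 were higher with each acid, namely far-3, irg-3, fat-5, acds-10, dhrs-4, decr-1.1, T25G12.13, acs-7, acox-1.1 and lys-4, and clec-174 was lower with each. The carnitine palmitoyltransferase gene cpt-4 turned with the acid, at -1.05 with LNA, -0.70 with GLA and 0.63 with DGLA. The acyl-CoA synthetase acs-7, acox-1.1 and the lysozyme lys-4 were chosen for naming here after their values were seen. In LNA against control the calls of acox-1.1 (0.113 to 0.206), acs-7 (0.0839 to 0.163) and lys-4 (0.0681 to 0.0963) ended without any 1 control array, LNA 2 or LNA 3, and in GLA against control that of lys-4 (0.105 to 0.206) ended without any 1 of the 6 arrays. The call of acox-1.1 with LNA ended after cyclic loess too.

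The 3 comparisons share their control arrays, so each overlap was set beside simulated unchanged groups with shared controls. LNA and GLA shared 10 probe sets higher and 3 lower, against 0.0205 and 0.00246 for independent lists and a simulated mean of 0.02 shared calls with 1 at most. LNA and DGLA shared 10 higher and 1 lower, with cpt-4 opposite, against 0.042 and 0.00594 for independent lists and a simulated mean of 0.02. GLA and DGLA shared 33 higher and 16 lower, with cpt-4 opposite, against 0.129 and 0.0475 for independent lists and a simulated mean of 0.01. The simulated groups hold no effects and so have almost no calls to share, and the independent lists leave out the shared controls, so the excess over either is not a measure of a shared effect, and part of it can come from the shared controls. Across probe sets, which are not independent replicates, fold changes correlated at 0.373 for LNA and GLA and 0.344 for LNA and DGLA, below the 0.5 and 0.501 that shared controls alone gave, and at 0.573 for GLA and DGLA, above the 0.501 they gave. The covariance of the fold changes was 0.0159, 0.0151 and 0.0212 in that order, against a simulated 0.0163. The simulation gave all arrays of a probe set the same spread. Unequal spread between groups can move these values either way, so the differences are not a measure of a shared effect. Without LNA 2 and LNA 3 the shared calls in the same direction were 5, 4 and 40 in place of 13, 11 and 49. The 3 control arrays are too few to give each comparison 2 controls of its own.

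The acids were also compared with each other at the same dose. Worms can turn LNA into GLA and GLA into DGLA, and no level of an acid in the worms was used here. A difference is therefore between supplements and cannot be laid to the structure of the acid. GLA against LNA compared the acid with the added double bond to the one without it. The cytochrome P450 gene cyp-13A12 was 16.3-fold higher with GLA than with LNA (log2 difference 4.03, 95% interval 3.71 to 4.34, adjusted p = 1.51e-07), and ugt-37 was 7.53-fold higher (2.91, 2.57 to 3.26, adjusted p = 7.72e-06). Higher too were far-3 (1.94, 1.41 to 2.47, adjusted p = 0.0157), the P-glycoprotein transporter pgp-1 (1.18, adjusted p = 0.0244) and ugt-35 (1.08, adjusted p = 0.00601). Lower with GLA were mbug-1 (-1.43, adjusted p = 0.00556), clec-247 (-1.24, adjusted p = 0.00109), the lysozyme lys-7 (-0.82, adjusted p = 0.0201), C17H12.8 (-0.65, adjusted p = 0.0348) and the lipase-related lips-5 (-0.62, adjusted p = 0.0456). In limma's test 18 probe sets passed, for 10 genes higher and 6 lower with no overlap of arrays, as was so for 15.2% of all genes, where chance gives 10%.

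Of 67 genes called with GLA or LNA against control, 11 differed between the acids. In 48 the 95% interval of the difference lay within 2-fold, and in 9 that were not called it reached beyond (median interval half-width 0.283). Here and in the other comparisons between acids these counts overlap, since a called difference can have an interval within 2-fold. The share of the 18 calls that were higher was 55.6%. It was 75% after cyclic loess, 72.7% after median centring, 66.7% with the length trend removed and 50% without LNA 2 and LNA 3, and went from 40% without dim probe sets to 83.6% without LNA 1, so the balance of directions was not settled. Calls of cyp-13A12, ugt-37, mbug-1 and clec-247 held whichever array was left out. Those of far-3 (0.0796 to 0.122) and pgp-1 (0.105 to 0.165) ended without LNA 3 or any 1 GLA array, that of ugt-35 (0.0564 to 0.0582) without LNA 3 or GLA 3, and those of lys-7 (0.0796 to 0.165), C17H12.8 (0.0984 to 0.234) and lips-5 (0.107 to 0.249) without LNA 2, LNA 3 or any 1 GLA array. The count of 18 was 961, with 803 higher and 158 lower, without LNA 1, 11 without LNA 2, 4 without LNA 3, 6 without GLA 1, 5 without GLA 2 and 4 without GLA 3. Without LNA 2 and LNA 3 it was 12, of which 5 were among the 18, and the calls of pgp-1, mbug-1, lys-7, C17H12.8 and lips-5 ended. On the 6 arrays alone it was 3, and the calls of far-3, pgp-1, ugt-35, clec-247, lys-7, C17H12.8 and lips-5 ended. Those of C17H12.8 and lips-5 ended after cyclic loess, and that of C17H12.8 with the length trend removed.

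Innate immune effectors were lower with GLA than with LNA as a set (2 of 46 fell, or 11 with 1 higher adjusted over the list alone, median -0.19, adjusted p = 0.00132, adjusted p = 0.986 with an estimated correlation), and this call held with any 1 array left out but ended without both LNA 2 and LNA 3. Molting genes were higher (median 0.04, adjusted p = 0.0174), and neuropeptides (median -0.12, adjusted p = 0.00578), proteasome genes (median -0.09, adjusted p = 0.0321) and respiratory chain genes (median -0.10, adjusted p = 0.0472) were lower, with no member passing on either adjustment. For each of these 4 lists too adjusted p = 0.986 with an estimated correlation. With the length trend removed the respiratory (median 0.02, adjusted p = 0.574) and proteasome (median 0.02, adjusted p = 0.613) shifts turned direction without passing. The molting and neuropeptide calls ended there too. Without both LNA 2 and LNA 3 the neuropeptide and proteasome tests turned direction. The respiratory, neuropeptide and proteasome calls ended after cyclic loess, and the respiratory and proteasome calls without dim probe sets. The call of molting ended without LNA 3 (0.177) or GLA 1 (0.0835), of neuropeptides (0.051 to 0.224) and respiratory chain genes (0.114 to 0.244) without LNA 2, LNA 3 or GLA 3, and of proteasome genes (0.0626 to 0.37) without LNA 2, LNA 3, GLA 2 or GLA 3. The count of 5 lists was 9 without LNA 1, 3 without LNA 2, 2 without LNA 3 and 2 without GLA 3. It was 3 without LNA 2 and LNA 3, and 0 of the 5 were among them. In LNA 1, LNA 2 and LNA 3 the effectors deviated from their 12-array mean by 0.049, 0.154 and 0.137, the molting genes by 0.045, -0.115 and -0.138, and the proteasome genes by -0.029, 0.118 and 0.07.

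DGLA against GLA compared the elongated acid to the one before it in the pathway. With DGLA, nta-1 was 3.23-fold higher (log2 difference 1.69, adjusted p = 0.000417), cdr-4 was 2.53-fold higher (1.34, 95% interval 1.15 to 1.53, adjusted p = 6.97e-05) and cpt-4 was 2.51-fold higher (1.33, 1.14 to 1.52, adjusted p = 6.97e-05), at 8.33 ± 0.0554 against 6.997 ± 0.119. The steroid dehydrogenase family gene stdh-2 (1.66, adjusted p = 0.027) and T16G1.6 (1.27, adjusted p = 0.000397) were also higher. Lower with DGLA were ugt-37 (-2.01, -2.35 to -1.67, adjusted p = 0.000318), irg-5 (-1.50, adjusted p = 0.0403), cyp-13A12 (-1.33, adjusted p = 0.00425), clec-174 (-1.09, adjusted p = 0.0415) and F09C8.1 (-1.06, adjusted p = 0.0323). In limma's test 22 probe sets passed, for 7 genes higher and 10 lower with no overlap of arrays, as was so for 10.8% of all genes, where chance gives 10%.

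Of 154 genes called with either of these acids against control, 17 differed between them, 126 had an interval within 2-fold and 12 reached beyond uncalled (median half-width 0.281). Calls of nta-1, cdr-4, cpt-4, T16G1.6, ugt-37 and cyp-13A12 held whichever array was left out. Those of F09C8.1 (0.0664 to 0.19) ended without any 1 GLA array, DGLA 2 or DGLA 3, of stdh-2 (0.0725 to 0.19) without any 1 GLA array, DGLA 1 or DGLA 3, and of clec-174 (0.0725 to 0.23) and irg-5 (0.081 to 0.226) without any 1 of the 6 arrays. The count of 22 was 8 without GLA 1, 9 without GLA 2, 8 without GLA 3, 11 without DGLA 1, 11 without DGLA 2 and 8 without DGLA 3. Without LNA 2 and LNA 3, which enter here only through the spread, it was 21, of which 18 were among the 22, and the calls of stdh-2 and clec-174 ended. On the 6 arrays alone it was 13, of which 12 were among the 22, and the calls of stdh-2, clec-174 and F09C8.1 ended. That of clec-174 ended after cyclic loess and with the length trend removed too.

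Innate immune effectors were lower with DGLA than with GLA (3 of 46 fell, or 10 with 1 higher adjusted over the list alone, median -0.09, adjusted p = 3.24e-05, adjusted p = 0.59 with an estimated correlation), and autophagy genes were higher with no member passing (median 0.10, adjusted p = 0.000438, adjusted p = 0.59 with an estimated correlation). Both calls held whichever array was left out. Beta-oxidation (1 higher, or 1 with 1 lower adjusted over the list alone, median 0.08, adjusted p = 0.00181), peroxisome biogenesis (1 higher adjusted over the list alone, median 0.11, adjusted p = 0.00182), desaturases and elongases (median 0.09, adjusted p = 0.00411), lipases (1 higher adjusted over the list alone, median 0.05, adjusted p = 0.0133), phosphatidylcholine and SAM synthesis (median 0.08, adjusted p = 0.0298) and neuropeptides (median 0.07, adjusted p = 0.0427) were higher as sets, and ribosomal proteins lower (median -0.05, adjusted p = 0.00679). With an estimated correlation these had adjusted p = 0.743, 0.669, 0.719, 0.669, 0.669, 0.865 and 0.87. The calls ended without DGLA 1 for beta-oxidation (0.334) and peroxisome biogenesis (0.156), without GLA 3 or DGLA 1 for desaturases (0.0729 and 0.156), and without GLA 2 or DGLA 1 for lipases (0.106 and 0.114). They ended without GLA 1, GLA 2 or DGLA 1 for phosphatidylcholine and SAM synthesis (0.0861 to 0.405), without GLA 3, DGLA 1 or DGLA 3 for neuropeptides (0.0509 to 0.897), and without GLA 1, GLA 2 or DGLA 2 for ribosomal proteins (0.098 to 0.311). The count of 9 lists was 3 without DGLA 1, and all 9 stayed called without LNA 2 and LNA 3. With the length trend removed the calls of lipases, phosphatidylcholine and SAM synthesis and neuropeptides ended, that of neuropeptides ended after cyclic loess, and those of neuropeptides and phosphatidylcholine and SAM synthesis ended without dim probe sets.

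DGLA against LNA spanned both structural steps. With DGLA, nta-1 was 6.58-fold higher (log2 difference 2.72, 95% interval 2.41 to 3.03, adjusted p = 3.64e-06), cyp-13A12 was 6.47-fold higher (2.69, 2.38 to 3.01, adjusted p = 3.64e-06), gst-33 was 4.43-fold higher (2.15, 1.72 to 2.58, adjusted p = 0.000514) and cdr-4 was 4.03-fold higher (2.01, adjusted p = 1.35e-06). T16G1.7 was higher too (1.97, adjusted p = 0.00771), as were far-3 (1.80, adjusted p = 0.00785), cpt-4 (1.68, adjusted p = 3.64e-06) and the desaturase fat-7 (0.99, adjusted p = 0.0274), which were chosen for naming here after their values were seen. Lower with DGLA were irg-5 (-1.80, -2.29 to -1.32, adjusted p = 0.00466), cyp-35D1 (-1.43, adjusted p = 0.00307), F55G11.8 (-1.33, adjusted p = 0.000955), dct-17 (2.47-fold, adjusted p = 0.011) and dod-17 (-1.29, adjusted p = 0.0175), a gene downstream of DAF-16. In limma's test 93 probe sets passed, for 31 genes higher and 53 lower with no overlap of arrays, as was so for 12.7% of all genes, where chance gives 10%.

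Of 143 genes called with DGLA or LNA against control, 56 differed between the acids, 81 had an interval within 2-fold and 16 reached beyond uncalled (median half-width 0.284). The share of the 93 calls that were higher was 37.6%. It was 48.5% after cyclic loess, 50.5% with the length trend removed and 54.8% without LNA 2 and LNA 3, and went from 32% with the trend and robust options to 70.1% without LNA 1, so the balance of directions was not settled. The calls of dod-17 (0.0665 to 0.0887) ended without LNA 2, LNA 3, DGLA 2 or DGLA 3, of dct-17 (0.0573 to 0.066) without LNA 3, DGLA 2 or DGLA 3, of far-3 without DGLA 2 (0.0504) and of fat-7 (0.068 to 0.105) without LNA 2 or any 1 DGLA array. Those of nta-1, cyp-13A12, gst-33, cdr-4, T16G1.7, cpt-4, irg-5, cyp-35D1 and F55G11.8 held whichever array was left out. The count of 93 was 1359, with 952 higher and 407 lower, without LNA 1, 47 without LNA 2, 45 without LNA 3, 39 without DGLA 2 and 41 without DGLA 3. It was 31 without LNA 2 and LNA 3, of which 21 were among the 93, and the calls of irg-5, cyp-35D1, dct-17 and dod-17 ended. On the 6 arrays alone it was 22, and the calls of T16G1.7, irg-5, dct-17, dod-17, far-3 and fat-7 ended.

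Innate immune effectors were lower with DGLA than with LNA (9 of 46 fell, or 18 with 2 higher adjusted over the list alone, median -0.23, adjusted p = 6.81e-10, adjusted p = 0.187 with an estimated correlation), and ribosomal proteins were lower as a set with no member passing (median -0.09, adjusted p = 6.55e-05, adjusted p = 0.833 with an estimated correlation). Both calls held with any 1 array left out. The ribosomal shift turned direction without both LNA 2 and LNA 3 (median 0.01). It did so too with the length trend removed, without passing (median 0.04, adjusted p = 0.36). The ribosomal list deviated from its 12-array mean by -0.043, 0.15 and 0.1 in LNA 1, LNA 2 and LNA 3. Autophagy (median 0.03, adjusted p = 0.0203), molting (1 higher adjusted over the list alone, median 0.05, adjusted p = 0.0218), body wall muscle (median 0.08, adjusted p = 0.0218), peroxisome biogenesis (3 higher adjusted over the list alone, median 0.08, adjusted p = 0.0252) and beta-oxidation (1 of 43 higher and 3 lower, or 11 and 6 adjusted over the list alone, median 0.03, adjusted p = 0.0308) were higher as sets, and respiratory chain genes lower (median -0.09, adjusted p = 0.0407). For each of these adjusted p = 0.833 with an estimated correlation. With the length trend removed the respiratory shift turned direction without passing (median 0.02, adjusted p = 0.798) and the molting call ended. The respiratory call ended after cyclic loess. The molting and muscle tests turned direction without both LNA 2 and LNA 3. The calls ended without LNA 3 or DGLA 1 for autophagy (0.119 and 0.0979), without LNA 2 or LNA 3 for muscle (0.117 and 0.0888) and molting (0.0628 and 0.174), and without LNA 1, LNA 3 or DGLA 1 for beta-oxidation (0.122 to 0.379) and peroxisome biogenesis (0.0888 to 0.306). For respiratory chain genes (0.0694 to 0.268) the call ended without LNA 2, LNA 3, DGLA 2 or DGLA 3. The count of 8 lists was 3 without LNA 3. It was 7 without LNA 2 and LNA 3, of which 3 were among the 8, and the calls of molting, autophagy, ribosomal, respiratory chain and muscle genes ended. In LNA 1, LNA 2 and LNA 3 the muscle markers deviated from their 12-array mean by 0.168, -0.527 and -0.419, and the autophagy genes by 0.019, -0.083 and -0.124.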

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

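The alternatives without arrays LNA 2 and LNA 3, with the length trend removed, with repeated probe sets counted once, and with single genes fitted on 6 arrays were chosen only after the result was seen. Counts below follow the order LNA, GLA and DGLA against control, GLA against LNA, DGLA against GLA and DGLA against LNA, where 17, 67, 146, 18, 22 and 93 probe sets were called. They were 0, 27, 66, 3, 13 and 22 on only the 6 arrays compared, which leaves fewer samples for the spread. In limma's fit of 12 arrays LNA against control had 2814 probe sets at an unadjusted p under 0.05. GLA and DGLA against control, with more calls, had 1600 and 1668, so this number did not follow the calls. The counts were 37, 90, 192, 29, 23 and 175 with the trend and robust options, and 10, 33, 63, 8, 14 and 40 with a fold limit of 2, a stricter rule by construction. With the replicate block they were 6, 55, 108, 8, 11 and 56, and since the numbers are not known to pair samples (same-number correlations of residuals -0.133 to 0.216, median 0.00719, against a median of 7.15e-05 for other pairs), a call lost there was not read as a weaker effect. Further changes were 209 for DGLA against LNA with array weights, 140 without dim probe sets, 51 with the ordinary model (67 for DGLA against control) and 31 without LNA 2 and LNA 3, and 11 for GLA against LNA after median centring. The fit without LNA 2 and LNA 3 leaves LNA with 1 array, assumed to vary like the other groups. Where 1 array was left out, which leaves 1 group with 2 arrays, they ranged over 5 to 895, 24 to 54, 89 to 106, 4 to 961, 8 to 11 and 39 to 1359. The called lists, 6, 9, 15, 5, 9 and 8, were 0, 0, 1, 0, 0 and 0 with an estimated correlation and 1, 0, 5, 0, 0 and 1 with fry. GLA against LNA had 3 with the block, 3 without dim probe sets, 3 without LNA 2 and LNA 3 and 8 with the length trend removed, of which 3, 3, 0 and 1 were among its 5, and LNA against control had 2 without LNA 2 and LNA 3. With 1 array left out the lists ranged over 5 to 12, 7 to 10, 8 to 17, 2 to 9, 3 to 10 and 3 to 12. Shared calls of LNA with GLA and with DGLA were 5 and 4 without LNA 2 and LNA 3. The test of a list turned direction without LNA 2 and LNA 3 for ribosomal proteins (LNA against control, median 0.01473; GLA against LNA, 0.06533; DGLA against LNA, 0.009233), neuropeptides (LNA against control, -0.005865; GLA against LNA, 0.01485), proteasome (GLA against LNA, -0.002365), molting (-0.04229), germline (-0.08522) and muscle (-0.04167, all DGLA against LNA). It turned with the length trend removed for ribosomal proteins (0.07465 in GLA against LNA and 0.04145 in DGLA against LNA), respiratory chain (0.01664 and 0.01922) and proteasome (0.02487 in GLA against LNA), and without control 3 for oocyte genes (GLA against control, -0.004302, with -0.1587 the lowest with 1 array left out). Apart from fewer samples and the stricter rule, the cause was not tested. Of 182 named gene calls none reversed, and 6 were lost with cyclic loess, 5 with the length trend removed, 50 with the block, 59 without LNA 2 and LNA 3, 99 on 6 arrays and 86 without at least 1 array, with 0 of 175 lost without dim probe sets. Of 52 list calls 51 were lost with an estimated correlation, 45 with fry, 9 with cyclic loess, 7 without dim probe sets, 4 with the block and 2 with median centring. Of the same 52, 33 were lost and 1 reversed without at least 1 array, 8 were lost and 7 reversed without LNA 2 and LNA 3, and 10 were lost and 4 reversed with the length trend removed. A call was counted as reversed when its test changed sign, whether or not it passed in the new direction. With the length trend removed the 4 reversed calls did not pass in camera (adjusted p 0.36 to 0.798). Nor did the oocyte call without control 3 (0.948), whose median kept its sign. Without LNA 2 and LNA 3 the medians of the 7 reversed calls were small, between -0.04229 and 0.01485. Signal over background limits what dim genes can show, and no detection value per probe set was used here.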

Other observations

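Of the tests in this part, those of gene length among brighter genes, of stage for arrays LNA 2 and LNA 3, of intestinal RNA, of gene length for the immune effectors and for beta-oxidation, of peroxisomal against mitochondrial enzymes, of gene families and of other splits of the arrays were chosen only after the result was seen. Bootstrap intervals in this part resample genes measured on the same arrays, so they leave out the spread between arrays. Among families read from gene names, the 28 short-chain dehydrogenases of the dhs family were higher as a set with each acid (median 0.14 with LNA, adjusted p = 0.00448, median 0.05 with GLA, adjusted p = 0.0252, median 0.05 with DGLA, adjusted p = 0.00995). Of them 2 passed singly with GLA and 4 with DGLA, and with an estimated correlation the set had adjusted p = 0.909, 1 and 0.998. The 14 P-glycoprotein genes were higher as a set with DGLA (median 0.06, adjusted p = 0.0451, 0.998 with an estimated correlation) with 1 passing singly. The mitochondrial ribosomal proteins of the large (41 genes, median 0.11, adjusted p = 0.000407) and small subunit (29 genes, median 0.15, adjusted p = 0.000113) were higher as sets with LNA and not singly (adjusted p = 0.909 with an estimated correlation for both). The cest (34 genes), slc (33), rab (19) and pho (11) families were also higher as sets with LNA (adjusted p = 0.00844, 0.00844, 0.0252 and 0.0252), and the 32 guanylyl cyclases of the gcy family were lower (median -0.12, adjusted p = 0.0252). No member of these 5 families passed singly with LNA, and each family had adjusted p = 0.909 with an estimated correlation. The families were not fitted without LNA 2 and LNA 3 or with the length trend removed. The ribosomal protein list, also higher with LNA, lost its call with that trend removed and turned direction without those arrays. Whether the family shifts with LNA rest on the same arrays was not tested.

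Within beta-oxidation, the 10 peroxisomal enzymes had a median log2 fold change of 0.39 with LNA (95% bootstrap interval 0.29 to 0.61), 0.43 with GLA (0.14 to 0.89) and 0.57 with DGLA (-0.03 to 1.15). The 26 mitochondrial enzymes had 0.17 (0.06 to 0.25), 0.06 (-0.0034 to 0.25) and 0.27 (-0.03 to 0.42). The list members ech-2, ech-3, ech-4, ech-5, ech-7, ech-8 and ech-9 were assigned to neither compartment and left out. The mean of peroxisomal minus mitochondrial genes was 0.308 higher in supplemented than in control arrays (exact two-sided permutation p = 0.00455, the smallest that the 220 arrangements can give), and all 9 supplemented arrays lay above every control array. A trend with gene length as the whole cause of the rise with DGLA was argued against, since genes outside the list that matched its 43 members in length and signal had a median of 0.0034 (bootstrap interval -0.0019 to 0.0142) where the list had 0.277. Length here is genomic span, and a trend with transcript length was not tested. A peroxisomal response to these acids may be what the list records, as a hypothesis found and tested on the same data, and whether it differs between the acids was not tested.

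Arrays LNA 2 and LNA 3 lie apart from the other 10 on the first principal component. Over all genes the higher of their Spearman correlations between gene length and deviation from the 12-array mean was 0.00849 (LNA 2, with LNA 3 at -0.13), a value set beforehand to count against a trend with gene length. The correlation was 0.0537 (LNA 2) and 0.011 (LNA 3) over the dimmer genes. Over the brighter genes it was -0.284 (LNA 2) and -0.342 (LNA 3) against -0.109 to 0.316 in the other arrays. A trend with gene length among brighter genes, as RNA integrity or labelling would give, may therefore contribute. Why the value over all genes differs was not tested. Less body wall muscle RNA was argued against, since the 9 shorter of 17 muscle markers had medians of 0.0365 (bootstrap interval -0.159 to 0.176) and -0.00662 (-0.0514 to 0.132) while the 8 longer ones had -1.24 and -0.656. A difference in stage stays open, since the vitellogenin mean was the lowest of all 12 arrays in LNA 2 (-0.992) but 0.483 SD of the other 10 arrays from their mean in LNA 3 (0.233), and the molting genes were low in both (-0.115 and -0.138) with only control 3 lower (-0.201). Also open is whether RNA quality, labelling or the culture set them apart, and the design names no difference between arrays of a group that could be tested.

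Innate immune effectors fell with DGLA, 12 of them singly with a median of -0.96. Less intestinal RNA as the cause of these 12 falls was argued against, since 18 intestine markers outside the list had a median of 0.0223 (bootstrap interval -0.000505 to 0.0557). By array, all 19 intestine markers deviated from their 12-array mean by 0.089, -0.009 and -0.042 in DGLA 1, DGLA 2 and DGLA 3. In control 1, control 2 and control 3 they deviated by -0.056, 0.019 and -0.005. This spread is wider than the interval but small beside -0.96, the median of effectors selected because they were called lower. It is not small beside the -0.154 of all 46 members. The test therefore does not decide on a smaller part of the shift of the whole list. A trend with gene length as the whole cause was argued against too, since genes outside the list that matched its 46 members in length and signal had a median of -0.00579 (-0.0153 to -0.00204) where the list had -0.154. Length here is genomic span, and a trend with transcript length was not tested. For a difference in stage, 10 of 12 stayed called with the vitellogenin mean as a covariate, and at least 10 was set beforehand to count against stage as the whole cause. The covariate moved 1948 probe sets by over 0.1, and the median of all 46 was -0.175 (-0.276 to -0.0951). The calls of irg-4 (-0.717, SE 0.129, before and -0.733, SE 0.138, after) and K08D8.5 (-0.881, SE 0.156, and -0.831, SE 0.159) ended at adjusted p = 0.0604 and 0.0652 as the SE grew, with a smaller fold only for K08D8.5. This test covers stage only as the vitellogenins record it, and that list passed with no acid. The molting and sperm lists, which shifted with DGLA, were not used as covariates, so a difference in stage stays open. Also open, and not tested, is whether the acid acted on the worms or through the bacterial food.

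Each comparison was fitted again on all 12 arrays with every split of its 6 arrays into 3 and 3 and the other 6 kept in their groups. Of the 10 splits 1, the real grouping, gave as many calls. The real grouping and the highest of the other splits gave 17 and 1 calls for LNA against control, 67 and 0 for GLA against control, 146 and 0 for DGLA against control, 18 and 1 for GLA against LNA, 22 and 0 for DGLA against GLA, and 93 and 2 for DGLA against LNA. These 10 splits are too few for a share under 0.05.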
